A study of Mus musculus with 4 samples.

How the data were processed

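The series holds 4 RNA-seq libraries of Jurkat cells, 2 labelled wild-type and 2 labelled MATR3 knockout, and 1 table with raw counts per gene, which the authors deposited without normalization. All 4 columns of read counts were used, each assigned by the short name in its sample's description. Total RNA was extracted with Trizol and libraries were made with Illumina protocols, per the labels' protocols. CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3 are named, per the submitters' processing notes. Their roles, the strand setting, the treatment of reads that match several places and the genome build are not given in the sources used here. The organism label says mouse, but all 58735 rows carry human Ensembl identifiers, per the file headers and rows, and the cell line is human, so the values were treated as human. Gene symbols, biotypes, lengths and coordinates were taken from the deposited table.

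Total counts per library ranged from 15008554 to 17477643. Such depths leave genes with few reads imprecise. MATR3 had 28 reads over the wild-type group, and the 95% exact conditional interval of its ratio of 4.16 was 2.72 to 6.56, which covers counting error only. Where a group had 0 reads, the fold is given as a lower bound against a floor of 3 counts over the group, which also covers counting error only. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies, such as histone, HLA, MAGE and ribosomal protein genes, have uncertain counts. Replicates of both groups differed beyond sampling noise (chi-square per gene 5.83 between the wild-type libraries and 2.21 between those labelled knockout, over genes with at least 20 reads), so each library was counted as 1 replicate.

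The main comparison used edgeR 4.0.16 under R 4.3.3, with TMM scaling (factors 0.978 to 1.04), its default expression filter (10 counts minimum, 15 in total) and a two-sided quasi-likelihood test of knockout against wild-type, with Benjamini-Hochberg adjustment over 15294 genes and a threshold of 0.05. No covariate was used. The common biological coefficient of variation was 0.0667. CPM values are scaled by the TMM factors, and standard errors are those of the log2 fold change. A total of 34 gene lists, among them markers of 6 other cell types and 2 lists on RNA quality, were fixed before the data were examined, and 891 of their 915 symbols were in the table. List shifts were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and adjusted over the 34 lists. Shifts per chromosome and per run of 50 neighbouring genes, taken every 10 genes, were compared with permuted gene orders. The relation to GC content was not tested, because no human genome was used here.

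The genes named in the text follow a rule fixed before the data were examined. It takes the MATR3 rows and up to 4 of the most changed members of each list. It also takes the 12 largest rises and 12 largest falls by fitted log2 fold change. These were drawn from protein-coding genes that passed the test, had no overlap between the groups and averaged at least 5 CPM. Some genes that the rule takes are not reported here. Additional list members are named as examples, chosen after their values were seen, as were the genes on chromosome 9 other than KLHL9 and the genes of the run on chromosome 1.

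The alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling, no composition factor, the DESeq2 1.42.0 Wald test, limma voom, no expression filter, 1 CPM in at least 2 libraries, protein-coding genes only, 2 stricter thresholds, a block on the replicate number, leaving out each library in turn, camera with an estimated correlation, fry, and position and length checks on genes averaging at least 5 CPM. A restriction to genes at 1 CPM or more in both wild-type libraries was added after the data were seen.

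The test was run first on counts simulated from the wild-type means, with the depths and dispersions of these libraries, 2 against 2. Of 15294 simulated genes, 200 were changed, equally up and down, and 14157 genes passed the filter and were tested. So few and balanced changes do not show how scaling or false calls behave in the real comparison, where 66.0% of genes were called. It recovered 76% of the genes changed 2-fold and 90% of those changed 4-fold, and 13 of its 179 calls (7.26%) were false. Camera called the 1 list that had been moved, and 2 of the 33 tested in all.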

Results

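RNA sequencing read counts per gene were analysed from Jurkat cells, a human T cell leukaemia line, labelled wild-type or MATR3 knockout by CRISPR-Cas9. MATR3 encodes matrin 3, an RNA-binding protein of the nuclear matrix. The series title places the work in the epigenetic control of CD4 T cell immunity in liver cancer, and the design text names 1 comparison, knockout against wild-type. Each group held 2 libraries. The total counts were 17477643 and 15400214 in wild-type replicates 1 and 2, and 15008554 and 15022788 in replicates 1 and 2 labelled knockout. Of 58735 gene rows, 30729 had 0 reads in all 4 libraries and 15294 passed the expression filter and were tested. Spearman's correlation across genes was 0.994 between the wild-type libraries, 0.995 between the libraries labelled knockout and 0.909 between replicate 1 of each group. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

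The tested row of the targeted gene held few reads, with more in the libraries labelled knockout. MATR3 (ENSG00000015479, chromosome 5, 139293648 to 139331677, genome build not given in the sources used here) stood at 0.828 ± 0.372 CPM (SD, n = 2) in wild-type and at 3.49 ± 0.882 CPM (SD, n = 2) in the libraries labelled knockout. The reads behind these values were 19 and 9 in wild-type, and 42 and 61 in the libraries labelled knockout. The log2 fold change was 2.05 (SE 0.384, adjusted p = 2.85e-06, edgeR quasi-likelihood test), and it ranged from 1.66 without wild-type replicate 2 to 2.63 without wild-type replicate 1. A second MATR3 row (ENSG00000280987, chromosome 5, 139273752 to 139331671) held 5 and 1 reads in wild-type and 2 and 2 in the others, and was too low to test. The 2 rows overlapped over 38024 bases, 99.98% of the shorter row, and reads in the shared part may have been counted for neither, so these rows check nothing about the knockout. The neighbouring genes SNHG4 and PAIP2 stood at 42.5 and 39.5 CPM in wild-type. All directions below are therefore those of the libraries labelled knockout against wild-type.

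The libraries labelled knockout differed from wild-type across much of the transcriptome. The 12 largest rises and 12 largest falls were genes of mixed function. The granulocyte genes ELANE and CSF3R were among the rises, and the stem cell marker CD34 and the chemokine receptor gene CXCR3 among the falls. ELANE, the neutrophil elastase gene (ENSG00000197561, chromosome 19, 851014 to 856247), had 0 reads in wild-type and 28.8 ± 0.0464 CPM (SD, n = 2) in the libraries labelled knockout. This was at least 319.6-fold higher, taking a floor of 3 counts over the wild-type group. The other 11 largest rises by fitted log2 fold change were each also from 0 wild-type reads. Among them CSF3R, the granulocyte colony-stimulating factor receptor, was at least 245-fold higher and LYN, a kinase of myeloid and B cells, at least 139.8-fold higher. THEM4, DHRS9, SKAP2, STEAP3, SLC7A2, SLC2A5, UGGT2, A2ML1 and KLHL9 were at least 140.2-fold to 258.9-fold higher. The largest fall was in MAGEA12, a cancer-testis antigen gene, which went from 13.6 ± 0.193 to 0.304 ± 0.237 CPM (SD, n = 2 each). CD34, a stem and progenitor cell surface marker (ENSG00000174059, chromosome 1, 207880972 to 207911402), fell from 24.0 ± 0.848 to 1.19 ± 0.0381 CPM (SD, n = 2 each). SIX6, a homeobox gene, fell from 88.3 ± 3.63 to 6.24 ± 0.339 CPM, and ALDH1A2, a retinoic acid-synthesising enzyme, fell by 3.30 on the log2 scale (SE 0.098). Further large falls were in MAT1A, GFRA3, CXCR3, FABP6, FA2H, GALNT18 and PWP2, with log2 fold changes from -3.65 to -2.82. MAGEA12 and PWP2 have close relatives or copies in the genome between which reads can be split, so their levels are uncertain. PWP2 also lies in a run of neighbouring genes on chromosome 21 that was lower as a whole (39184176 to 44936954, median -0.81).

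By edgeR's quasi-likelihood test, 10088 of 15294 genes (66.0%) passed an adjusted p of 0.05, 5147 higher and 4941 lower. Of these, 4016 changed at least 2-fold, 2379 higher and 1637 lower. Changes of at least 16-fold were counted for 535 higher and 18 lower genes. Among genes at 50 CPM or more in the libraries labelled knockout, 42 of 4059 stood below 2% of that level in wild-type. In the other direction this held for 0 of 4115 genes, and the lowest was SIX6 at 7.07% of its wild-type level. The share of changed genes was 70.0% of 12768 protein-coding genes, 52.4% of 540 lincRNAs, 41.3% of 699 antisense genes and 37.2% of 409 processed pseudogenes, and differences between these shares were not tested.

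**Figure D1:**
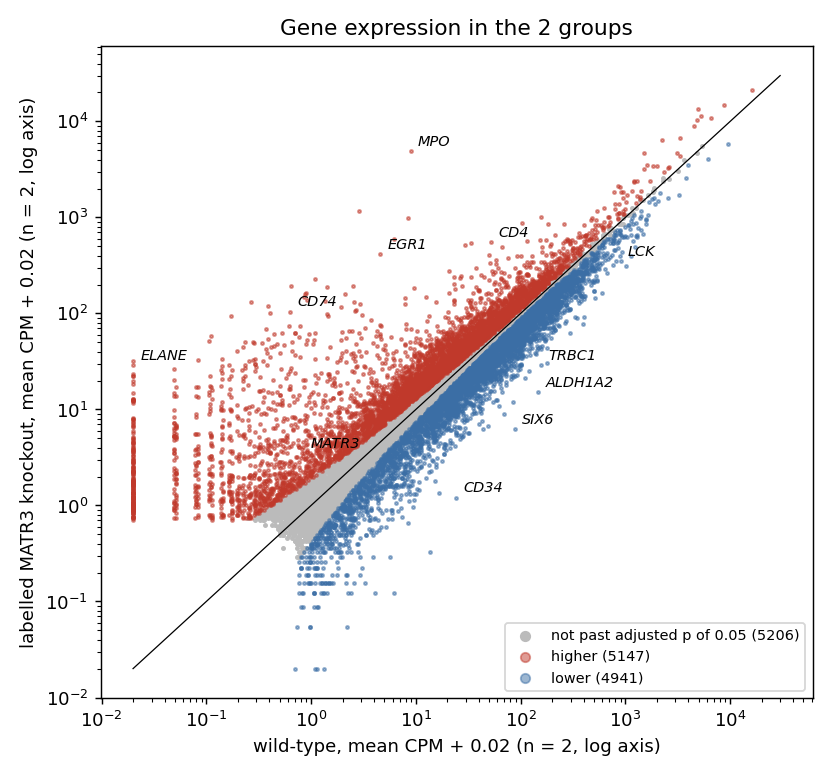
Mean expression of the 15294 tested genes in wild-type (x axis) and in the libraries labelled MATR3 knockout (y axis), as CPM plus 0.02 on log axes, n = 2 per group. Red points are the 5147 genes higher and blue points the 4941 genes lower past an adjusted p of 0.05, and the line marks equal expression.

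Myeloid marker genes were at high levels in the libraries labelled knockout. MPO, the myeloperoxidase of granulocyte precursors (ENSG00000005381, chromosome 17, 58269856 to 58280935), stood at 8.93 ± 0.61 CPM in wild-type and 4920 ± 74.8 CPM in the libraries labelled knockout (SD, n = 2 each), a ratio of 552. MPO reads made up 0.486% and 0.480% of the counts in the libraries labelled knockout. CD33, a surface receptor of myeloid cells, rose from 0.206 ± 0.114 to 45.1 ± 0.757 CPM, and SPI1, the myeloid transcription factor PU.1, changed by 7.04 on the log2 scale. Of 12 myeloid markers tested, 11 were higher and 0 lower, with AIF1 at a log2 fold change of -0.07, and the median was 6.14. Camera gave an adjusted p of 9.44e-06 for this list, against an adjusted p = 0.455 with an estimated correlation. The summed CPM of all myeloid markers was 84.96 and 90.4 in wild-type, and 5432 and 5306 in the libraries labelled knockout.

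Markers of other cell types moved unevenly. All 4 epithelial markers tested, of 17 listed, were higher, with KRT18 at 3.71 ± 0.273 and 86.3 ± 1.43 CPM (SD, n = 2 each). The other listed markers had too few reads to be tested. KRT18 and KRT8 (mean 36.4 CPM) made up most of the summed level of all 17, 131.2 and 131.1 CPM in the libraries labelled knockout. SERPINA1 had 1 read in each wild-type library, so only its reads in the others let it be tested. Camera gave an adjusted p of 0.0168 for the list (adjusted p = 0.455 with an estimated correlation). CLDN4 no longer passed the test without wild-type replicate 2 (adjusted p = 0.146) or replicate 2 labelled knockout (adjusted p = 0.462). Of 6 natural killer cell markers, 5 were higher, led by TYROBP, an adaptor also counted among the myeloid markers, and NCAM1 was lower (camera adjusted p = 0.113). The call for NCAM1 was lost without replicate 1 labelled knockout (adjusted p = 0.0765). Of 4 B cell markers, PAX5 and BLNK were higher and SPIB and CD79A lower (camera adjusted p = 0.997). PAX5, a B lineage transcription factor, had 0 reads in wild-type and was at least 32.0-fold higher. Of 9 fibroblast and kidney-line markers, 2 were higher and 4 lower (camera adjusted p = 0.413), with SPARC at a log2 fold change of -1.94. Of 4 erythroid and megakaryocyte markers, only TFRC, the transferrin receptor, passed the test, and it was lower (log2 fold change -1.57, camera adjusted p for the list 0.805).

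**Figure D2:**
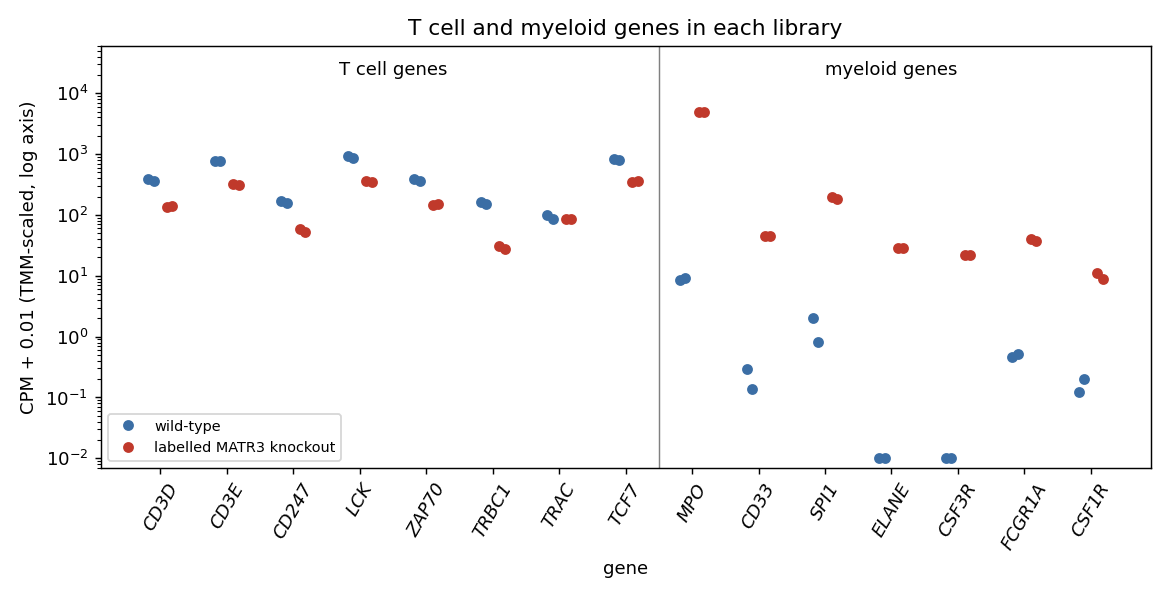
Expression of 8 T cell and 7 myeloid genes in each library, as CPM plus 0.01 on a log axis. Each point is 1 library, blue for wild-type and red for the libraries labelled MATR3 knockout. MPO stood at a mean of 8.93 CPM in wild-type and 4920 CPM in the others, while TRBC1 stood at 156 and 28.8 CPM.

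Genes of the T cell receptor complex and its proximal signalling were mostly lower. TRBC1, the constant region of the receptor beta chain (chromosome 7, 142791694 to 142793368), fell from 156.1 ± 8.14 to 28.8 ± 2.35 CPM (SD, n = 2 each). The log2 fold changes were -1.47 for CD3D, -1.26 for CD3E, -1.36 for the kinase gene LCK and -1.35 for ZAP70. CD4, the coreceptor for class II MHC, went the other way, from 51.98 ± 2.63 to 551 ± 10.4 CPM. LCP2, PTPN22 and PTPRC were also higher, while TRAC (log2 fold change -0.11) did not pass the test. Of 30 genes tested, 24 were lower and 4 higher, with a median of -0.99 and a camera adjusted p of 0.000148 (adjusted p = 0.455 with an estimated correlation). TRBC1 and TRBC2 are near-identical, so the split of reads between them is uncertain, and both lie in a run on chromosome 7 that was lower as a whole (141662922 to 150332721, median -0.79). The lower T cell receptor genes and the higher myeloid markers were found in the same 2 libraries.

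In the same 2 libraries, with their higher myeloid markers and mitochondrial share, the list around TAL1 and NOTCH was lower, with 18 of 26 genes lower and 6 higher (median -0.98, camera adjusted p = 0.0147, adjusted p = 0.455 with an estimated correlation). PTCRA, the pre-T cell receptor alpha chain, was at -2.42, TAL1 itself at -1.14 and RAG1, a recombinase of developing lymphocytes, at -1.19 on the log2 scale. LMO2, a partner of TAL1 in transcription complexes, and LYL1, a close relative of TAL1, were higher, LMO2 from 0.235 ± 0.155 to 31.6 ± 1.27 CPM and LYL1 from 20.8 ± 2.37 to 274.7 ± 6.74 CPM (SD, n = 2 each). Transcription factors of T helper lineages and T cell identity were lower for 17 and higher for 8 of 30 genes (camera adjusted p = 0.095), with STAT5A at -1.97 and TCF7 at -1.20. ZBTB7B, the CD4 lineage factor, was at 3.06. Homing and adhesion receptors were lower for 15 and higher for 5 of 25 genes (camera adjusted p = 0.0985). CXCR3, a chemokine receptor, fell by 3.08 on the log2 scale, whereas CD44, a hyaluronan receptor, rose from 0.144 ± 0.203 to 29.2 ± 0.434 CPM and ITGAL, the LFA-1 alpha chain, by 2.23 on the log2 scale.

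Inhibitory receptors and exhaustion-associated genes were higher for 7 and lower for 5 of 18 (camera adjusted p = 0.728, fry adjusted p = 0.008 with direction up). EOMES, a T-box factor of effector and memory cells, fell by 2.65 on the log2 scale, ENTPD1 (CD39) was higher by 2.61, and PDCD1 (0.32) and HAVCR2 (1.11) did not pass the test. Effector genes divided as 6 higher and 8 lower of 16 (camera adjusted p = 0.728). The chemokine gene CCL5 rose from 2.68 ± 0.763 to 107 ± 2.62 CPM, CXCL8, a neutrophil-attracting chemokine, from 0.690 ± 0.00144 to 24.1 ± 0.679 CPM, and the granzyme gene GZMB fell from 10.2 ± 1.35 to 1.46 ± 0.636 CPM (SD, n = 2 each). Activation and immediate-early genes were higher for 14 and lower for 5 of 24 (camera adjusted p = 0.0849). EGR1, an immediate-early transcription factor, rose from 4.55 ± 0.39 to 412 ± 7.15 CPM, and DUSP6, a phosphatase of the ERK pathway, by 3.73 on the log2 scale. NF-kB targets were higher for 14 and lower for 8 of 25 (camera adjusted p = 0.189), and here CXCL8, BCL2A1 and BCL3 led the rises and LTA the falls.

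Interferon-stimulated genes went both ways, with 14 higher and 10 lower of 32 (camera adjusted p = 0.997). IFIT3 was at 3.42 and IFIT2 at 2.56 on the log2 scale, while OAS2 was at -1.61. Of 18 genes of nucleic acid sensing, 8 were higher and 8 lower (camera adjusted p = 0.997), with CGAS, the cytosolic DNA sensor, at 0.501 ± 0.265 and 26.4 ± 2.13 CPM (SD, n = 2 each). MHC and antigen presentation genes were higher for 11 and lower for 6 of 25 (camera adjusted p = 0.436). CD74, the class II invariant chain, rose from 0.607 ± 0.208 to 104.7 ± 1.92 CPM, HLA-B from 66.4 ± 4.64 to 496 ± 16.3 CPM and HLA-E by 1.54 on the log2 scale. HLA genes share sequence and differ between alleles, so their read counts are uncertain.

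Genes of DNA replication and the G1/S transition were lower for 28 and higher for 4 of 34, with a median of -0.78 and a camera adjusted p of 4.84e-05 (adjusted p = 0.455 with an estimated correlation). GINS2, part of the replicative helicase, fell from 169 ± 11.1 to 53.4 ± 5.09 CPM and UHRF1, a cofactor of maintenance DNA methylation, from 356.6 ± 10.2 to 138.5 ± 2.59 CPM (SD, n = 2 each). Genes of G2/M and mitosis were higher for 14 and lower for 11 of 33 (camera adjusted p = 0.788), with CENPE at 1.23 and BIRC5 at -0.81. Cholesterol synthesis genes were lower for 16 and higher for 2 of 23 (median -0.57, camera adjusted p = 0.0147, adjusted p = 0.455 with an estimated correlation), with the enzyme genes LSS at -1.52 and SQLE at -1.09. LSS lies in a run on chromosome 21 that was lower as a whole (42916803 to 46254133, median -0.70). Genes of the ATF4 and unfolded protein response were higher for 18 and lower for 5 of 27 (median 0.54, camera adjusted p = 0.0155, adjusted p = 0.455 with an estimated correlation). SLC7A11, a cystine transporter, was at 3.04 and DDIT4, an mTORC1 inhibitor, at 2.73, while SDF2L1, a chaperone of the endoplasmic reticulum, was at -1.88. The 3 of these lists that passed camera moved in the libraries that also carried the myeloid markers.

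Other metabolic and stress lists did not pass camera. Glycolysis genes were higher for 10 and lower for 12 of 24 (camera adjusted p = 0.805), with PFKM at 3.95 and HK1 at -1.42. Nuclear-encoded genes of oxidative phosphorylation were higher for 5 and lower for 13 of 30 (camera adjusted p = 0.095). Hypoxia-response genes were higher for 13 and lower for 3 of 20 (camera adjusted p = 0.0985), heat shock genes higher for 3 and lower for 12 of 20 (camera adjusted p = 0.150), p53 targets higher for 8 and lower for 9 of 24 (camera adjusted p = 0.728), and apoptosis regulators higher for 13 and lower for 9 of 31 (camera adjusted p = 0.777). MCL1, an anti-apoptotic BCL2 family member, rose from 103.6 ± 3.62 to 869 ± 7.14 CPM, while BIK, a pro-apoptotic member, fell from 39.6 ± 0.45 to 10.6 ± 1.96 CPM (SD, n = 2 each).

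Among RNA-binding proteins associated with MATR3 and the nuclear matrix, 22 of 38 were lower and 10 higher (camera adjusted p = 0.280). LMNA, the lamin A/C gene, rose from 33.9 ± 3.23 to 237.5 ± 2.4 CPM and the paraspeckle RNA NEAT1 from 9.90 ± 1.01 to 35.9 ± 7.18 CPM (SD, n = 2 each), while the helicase gene DHX9 was at -1.24 on the log2 scale. SR proteins and spliceosome factors were higher for 14 and lower for 15 of 34 (camera adjusted p = 0.829). U2AF1 has a near-identical copy on chromosome 21, its level in the libraries labelled knockout was 23.8 ± 27.6 CPM, and its log2 fold change of 1.89 became -0.58 without replicate 2 of the libraries labelled knockout. Subunits of the SWI/SNF chromatin remodeller were higher for 11 and lower for 12 of 30 (camera adjusted p = 0.728), with ARID1B at 1.07 and BCL7C at -1.37. Polycomb, DNA methylation and histone-modifying enzymes were higher for 18 and lower for 14 of 39 (camera adjusted p = 0.728), with SETDB1, a histone H3 lysine methyltransferase, at 2.14 and TET2 at 1.74. SETDB1 lies in a run on chromosome 1 that was higher as a whole (148531385 to 151068497, median 1.94).

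Lists that track RNA quality also moved. All 15 mitochondrially encoded genes were higher, with a median of 1.01 and a camera adjusted p of 5.81e-05 (adjusted p = 0.572 with an estimated correlation). They took 5.31% and 4.92% of the counts in wild-type, and 9.49% and 9.33% in the libraries labelled knockout. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were higher for 8 and lower for 0 of 10 (median 1.94, camera adjusted p = 0.00934, adjusted p = 0.455 with an estimated correlation). The 4 largest rises among them lie in runs of neighbouring genes that were higher as a whole. HIST2H2BE and HIST2H2AC lie in a run on chromosome 1, which stayed higher without its histone, NBPF and pseudogene members (median 2.32). HIST1H2BK and HIST1H2AC lie in a run on chromosome 6 (26055787 to 30061640, median 1.17). That run holds other histone genes and was not recomputed without them, so it cannot tell RNA selection from a shift of the region. The summed level of the listed histone genes was 16.9 and 13.6 CPM in wild-type, and 98.99 and 101 CPM in the libraries labelled knockout. Cytosolic ribosomal protein genes were higher for 18 and lower for 8 of 38 (camera adjusted p = 0.413), led by RPS18 at 0.99.

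In all, camera called 9 of the 34 lists, 5 higher and 4 lower, and 0 with an estimated correlation, where 1 list (myeloid markers) had an unadjusted p under 0.05 and fry, which asks only whether the genes of a list move one way, called 24. Adjusted over the list alone, the counts of higher and lower genes were the same for 28 lists. They became 5 and 16 for homing receptors, 12 and 13 for SWI/SNF, 14 and 12 for G2/M, 14 and 9 for apoptosis, 4 and 12 for heat shock, and 9 and 0 for histones. The median and the mean differed in sign for 6 lists (nucleic acid sensing, SWI/SNF, MATR3-associated proteins, p53 targets, glycolysis and erythroid markers), and the median and camera's direction for 3 (SWI/SNF, SR proteins and B cell markers).

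**Figure D3:**
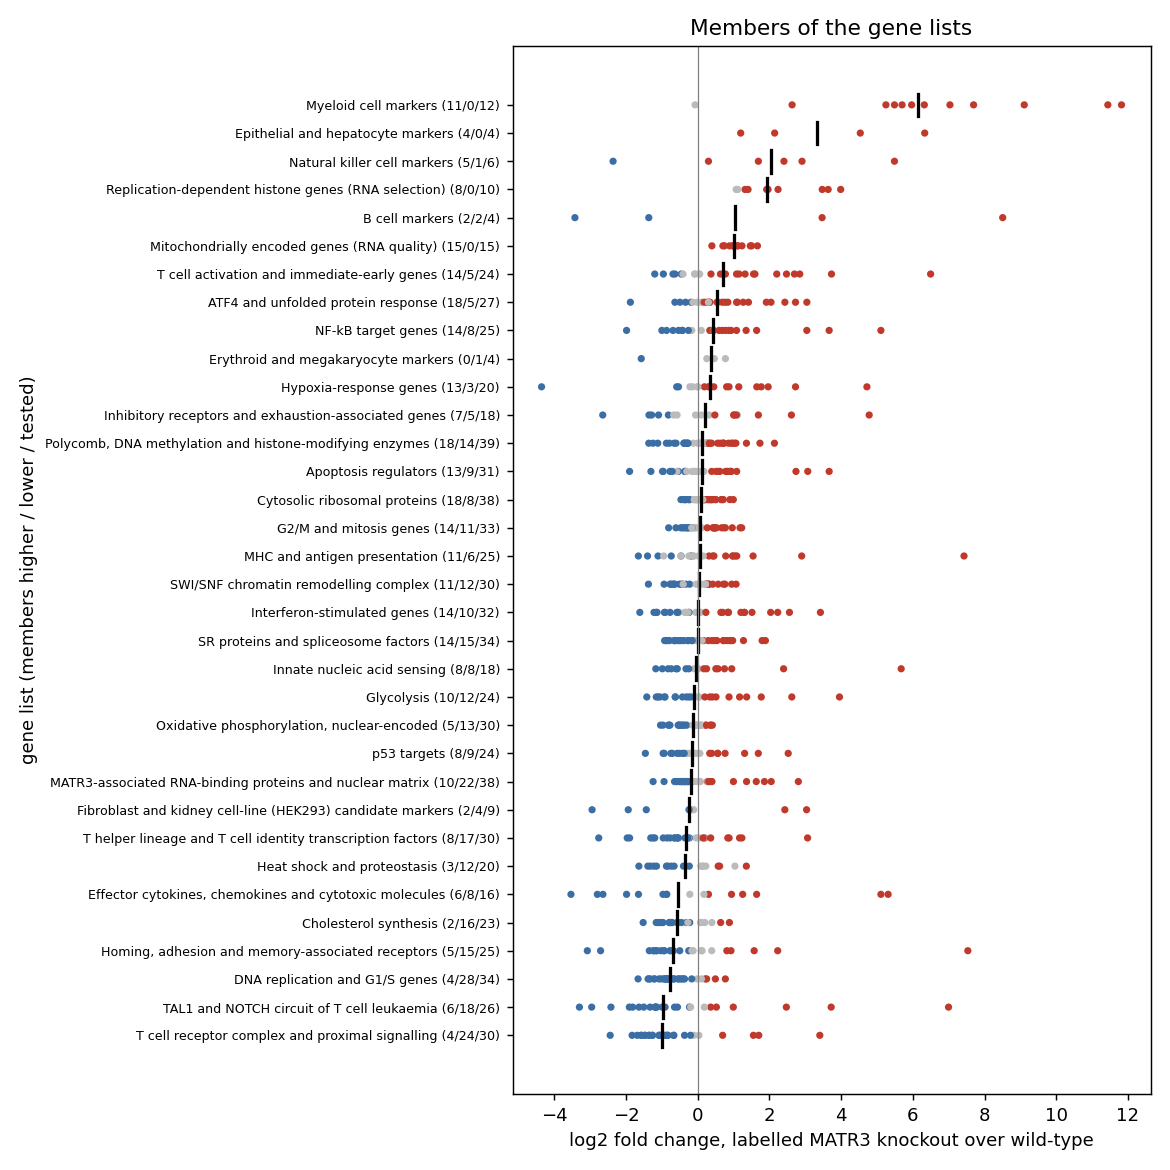
Log2 fold changes of the tested members of the 34 gene lists, libraries labelled MATR3 knockout over wild-type. Each point is 1 gene, red if higher and blue if lower past an adjusted p of 0.05 and grey otherwise, and black bars are list medians. The myeloid markers had the highest median (6.14) and the T cell receptor list the lowest (-0.99).

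Changes clustered along the genome. By permutation of gene order, 13 of 23 chromosomes had a shifted median, with the largest shifts on chromosome 13 (median log2 fold change 0.62 over 276 genes) and chromosome 21 (-0.40 over 166 genes), both at p = 1e-04, the smallest value that 10000 permutations can give. Runs of 50 neighbouring genes were taken every 10 genes, so that successive runs shared 40. Of 1422 such runs, 68 passed the threshold set by 1000 permuted gene orders, 58 higher and 10 lower. The 68 overlapped and formed 20 separate blocks, 16 higher and 4 lower, holding 1480 genes. The strongest lay on chromosome 1 from 147928393 to 150808323, between GPR89B and CTSK, with a median of 2.50, and it holds the myeloid marker FCGR1A, the histone genes HIST2H2BE and HIST2H2AC, MCL1 and the spliceosome gene PRPF3. Outside the shifted chromosomes and runs, 4188 of 6485 tested genes (64.6%) were changed. Gene length and GC content can vary along the genome and were not held fixed in the permutations. Their part in the shifts of chromosomes and runs was not tested.

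A further block was chosen after its values were seen, around KLHL9, 1 of the 12 largest rises. On chromosome 9, KLHL9 (21329671 to 21335380) had 0 reads in wild-type and 372 in the libraries labelled knockout, both libraries of a group summed. MTAP, a methionine salvage enzyme (21802543 to 21937651), had 1 and 603 reads, CDKN2A, a cell cycle inhibitor gene (21967753 to 21995301), 9 and 1479, and CDKN2B (22002903 to 22009363) 2 and 60. The flanking genes MLLT3 (log2 fold change 0.40) and HACD4 (-0.24) did not pass the test, and FOCAD was at 0.67. Gene length was weakly related to the log2 fold change (Spearman's correlation across genes 0.13, genes not being independent replicates). Split into 3 equal parts by length, the shortest genes had a median of -0.13 and the longest of 0.20.

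**Figure D4:**
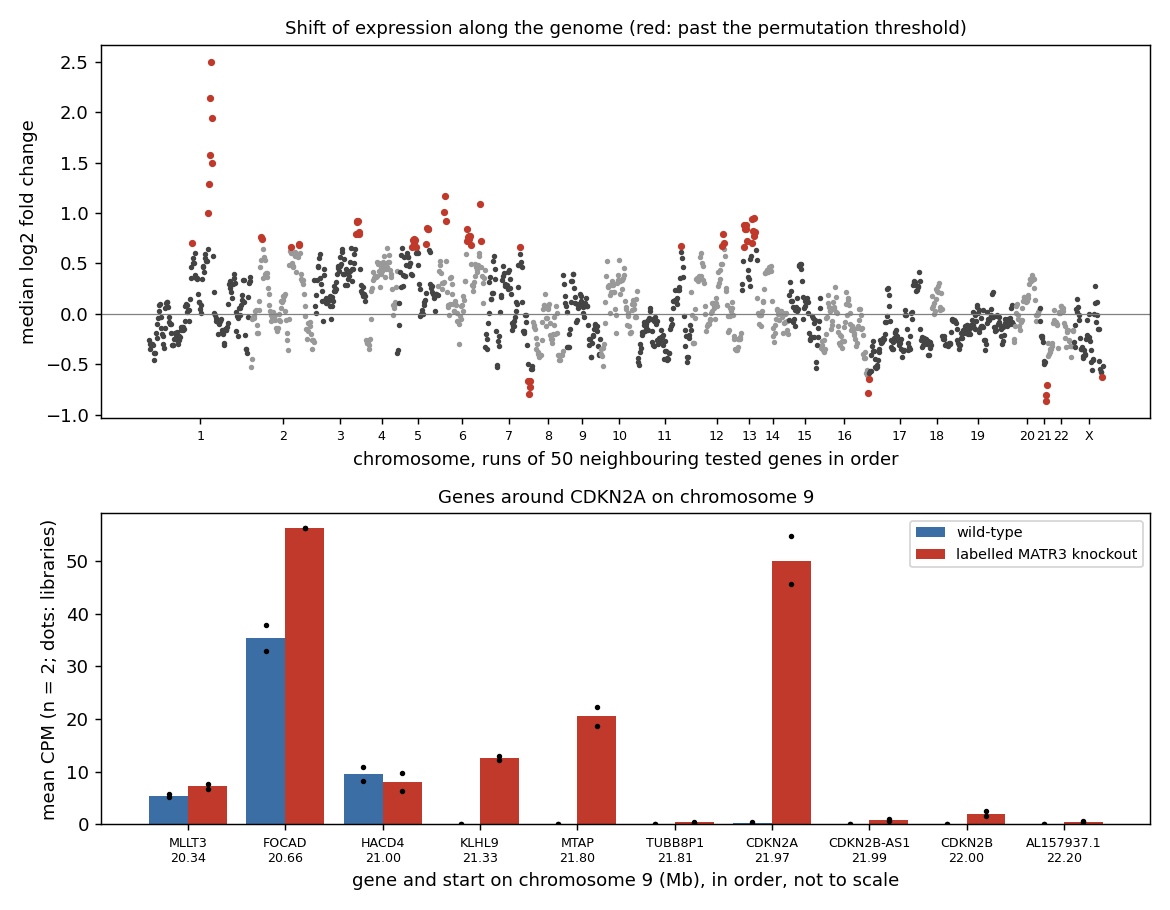
Top, median log2 fold change of each of 1422 overlapping runs of 50 neighbouring tested genes along the chromosomes, with the 68 runs past the permutation threshold in red. Bottom, mean CPM (bars, n = 2) and single libraries (dots) for genes around CDKN2A on chromosome 9, blue for wild-type and red for the libraries labelled MATR3 knockout. KLHL9, MTAP, CDKN2A and CDKN2B had 0, 1, 9 and 2 reads in wild-type.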

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

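The count of 10088 changed genes stayed between 8018 and 10263 when single libraries were left out, where the lone library of a group is assumed to vary like the other group, and between 8572 and 10142 under the other scalings, filters, tools and a threshold of 0.01. The restriction to genes expressed in wild-type, added after the data were seen, gave 8942. A required 2-fold change gave 4016, since that threshold removes smaller changes. Counting only outside the shifted chromosomes and runs gave 4188, since fewer genes were tested. The share of higher genes among those called lay between 47.8% and 53.4% over all scalings. Across genes, the log2 difference between replicates 1 and 2 in wild-type correlated at 0.0261 with that in the libraries labelled knockout. The replicate numbers thus gave no sign of pairing the samples. A replicate block gave 10072 genes, 9990 of them shared with the main count. The log2 fold change of MATR3 ranged from 1.66 to 2.63 without single libraries. Camera's 9 list calls became 0 with an estimated correlation and fry called 24, and leaving out single libraries gave 9 or 10. Under fry, which does not compare a list with other genes, the direction differed from camera's for 7 lists, of which 3 passed under fry, effector genes (adjusted p = 0.0104), nucleic acid sensing (adjusted p = 0.0315) and p53 targets (adjusted p = 0.0104), and the cause was not tested. The 147 named genes were followed under the alternative scalings, filters and tools, the replicate block and the removal of single libraries. Of the results for genes still tested there, 1878 kept their direction and side of the threshold, 20 kept only the direction and 1 reversed. The stricter thresholds and the restriction to genes expressed in wild-type were not followed per gene. The reversed one was U2AF1, which ranged from -0.58 without replicate 2 labelled knockout, which holds 642 of the 705 reads of its group, to 2.75 without replicate 1. The 20 others concerned CD160, MAF, IL7R, HLA-DPA1, NCAM1, CLDN4 and U2AF1. Runs past the position threshold numbered 69 with genes averaging at least 5 CPM, and the length correlation was 0.207 there. Depth limits genes with few reads, such as MATR3 with 28 wild-type reads.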

Other observations

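The tests of the genes around CDKN2A, of the receptor chain fractions, of the overlapping row pairs and of the run on chromosome 1 were chosen or revised after the results were seen. Outside the named genes, the receptor segments of the wild-type cells themselves could be followed. TRAV8-4, an alpha chain V segment, was the leading TRAV segment in all 4 libraries, with 89.9% (95% exact binomial interval 87.5 to 92.0) and 86.9% (84.1 to 89.3) of TRAV reads in wild-type and 81.6% (76.1 to 86.4) and 71.5% (65.4 to 77.1) in the libraries labelled knockout. The leading TRBV segment was TRBV12-3 in both wild-type libraries (41.8% and 40.4%), where TRBV7-2 was second with 129 and 131 reads. TRBV7-2 led in both libraries labelled knockout (24.7% and 47.7%), with 22 and 53 of 89 and 111 TRBV reads. It thus had fewer reads there too, and led after the larger fall of TRBV12-3. By edgeR's quasi-likelihood test, TRAV8-4 fell to 32.6% of its wild-type level, TRBV12-3 to 10.1% and TRBC2 to 36.2%, while TRAC stood at 92.6% and did not pass the test (adjusted p = 0.23).

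The run on chromosome 1 held changes in both directions. CTSS, a lysosomal protease of antigen-presenting cells, rose from 2.48 ± 0.582 to 191 ± 6.23 CPM, and RPRD2, TARS2 and ANP32E rose by 2.56, 2.52 and 2.08 on the log2 scale. In the same run BOLA1, SV2A and PLEKHO1 were lower, with log2 fold changes of -1.36, -1.02 and -1.31. These genes were chosen after their values were seen.

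Myeloid genes were higher and T cell receptor genes lower in the libraries labelled knockout. A change of transcription alone, in cells that all lack the block around CDKN2A, is argued against by reads from that block (KLHL9, MTAP, CDKN2A and CDKN2B, picked after their near-0 wild-type counts were seen), 11 and 1 in the wild-type libraries and 1208 and 1306 in those labelled knockout, a scaled ratio of 237 (95% interval 135 to 459, covering counting error only), but it stays open if the block was silenced rather than missing in wild-type, since no DNA was measured. Simple dilution of unchanged wild-type cells by RNA of other cells would leave TRAV8-4 and TRBV12-3 at 1 common fraction, if that RNA holds neither. Their log2 fold changes differed by 1.68 (SE 0.314), which argues against it for these 2 genes only. That does not exclude dilution. TRBV12-3 had 28 reads in the libraries labelled knockout. It lies in a lowered run on chromosome 7 (median -0.792), of which the cause was not tested. Of other chain genes, TRBC2 was left at 36.2%, near TRAV8-4 at 32.6%, but TRBC1 at 18.4% and TRAC at 92.6%. CD3D went from 395 and 357 CPM in wild-type to 133 and 138 CPM, and LCK from 946 and 860 to 361 and 342 CPM. These falls, like those of CD3E, CD247, ZAP70 and TCF7, were nearer the fraction of TRAV8-4 than that of TRBV12-3. SIX6, at 7.07%, and CD34, at -4.33 on the log2 scale, lay lower still, but were picked as largest falls. Of the 30 T cell receptor list genes, 4 were higher. An unrelated line alone is argued against by the lead of TRAV8-4, which held at least 71.5% of TRAV reads in each library, unless that line uses the same segment. The leading beta segment did change, to TRBV7-2, which was second in wild-type. Among what stays open are another stock of Jurkat cells with or without other cells and a mixture in which Jurkat cells had themselves changed. The source of any added RNA is not identified from the markers. Of the myeloid markers, 11 of the 12 tested (MPO at 4920 CPM, ELANE at 28.8 CPM) were higher in the same 2 libraries. So were all 4 epithelial markers tested (KRT18 at 86.3 CPM) and PAX5 (at least 32.0-fold, from 0 reads). The other epithelial markers, of 17 listed, had too few reads to be tested. Of the 4 B cell markers tested, 2 were lower. An effect of MATR3 loss on these genes stays open as untested, since the groups differ in all of this at once.

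MATR3 had few reads in all libraries and more in those labelled knockout. If reads in overlapping rows were left uncounted, other pairs of rows with the same name and strand should be low as well. Apart from MATR3 and 2 pairs without reads, 8 such pairs had a median summed level of 4.52 CPM against 14.6 CPM for 15982 other protein-coding rows with reads, a ratio of 0.311, between the bounds of 0.1 and 0.5 that had been set. Loss of shared reads and low expression therefore cannot be told apart from so few pairs, of which 3 were below 0.1 of the median of the other rows. The pairs were also chosen by overlap of their gene spans, not of exons, so some of them need not lose reads. The 2 pairs without reads that were left out could themselves be cases of such loss. Whether the knockout removed MATR3 in these cells cannot be read from either row.

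Genes between GPR89B and CTSK on chromosome 1 were higher together, with a median of 2.50. Chance placement is argued against by 1000 permuted gene orders, whose highest median was 0.764, and reads shared within the NBPF, histone and pseudogene families by a median of 2.32 over the 35 genes outside them, of which 30 were higher, 3 lower and 2 not past the test. A gain of copies in the cells labelled knockout, or other cells with more copies, may account for the run as a hypothesis, but the 3 lower genes go against one factor for all, and no DNA was measured. An effect of MATR3 loss on this run stays open as untested.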
